A study of Arabidopsis thaliana with 36 samples.

How the data were processed

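Expression was measured on 36 Affymetrix Arabidopsis arrays, 1 for each of 3 sucrose-gradient fractions (non-polysomal, small polysomal, large polysomal) of 12 extracts of aerial tissue from plants overexpressing CCA1, harvested at 4 times with 3 replicates each. Per the labels, RNA was labelled as biotinylated cRNA from oligo(dT)-primed cDNA. The deposited values are log2 expression values per probe set. The authors background-corrected, normalized and summarized them with GCRMA in R 3.1 with affy 1.42.3, and other settings are not stated. Values ran from 2.15 to 15.55, with a lower end shared by all arrays, so a difference between 2 low values is compressed.

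Of 22810 probe sets, 64 control probe sets were left out of the tests. Probe sets with a log2 value of 5 or more on at least 3 arrays, whatever their group, were kept, which left 12635. Of these 6824 name 1 gene, 263 name several and 5548 have no gene name in the annotation used here, so lists cover only part of their members. The probe set of CCA1 is among those not named, as are those of LHY, TOC1 and the PRR genes, and their levels are not reported. Where several probe sets name the same gene, the one with the highest mean over all arrays stood for it, for names and lists, which gave 6804 genes. Wild-type plants are not analysed here.

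Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to the log2 values, with 12 group means and 24 residual degrees of freedom. Adjusted p-values are from limma after Benjamini and Hochberg, and a probe set was called at an adjusted p under 0.05. The fractions were compared over the mean of the 4 times. The level of a transcript was the mean of its 3 fractions, and its loading the large polysomal minus the non-polysomal value. Light against dark compared the mean of 12pm and 6pm with the mean of 12am and 6am. Effects over the 4 times were tested with moderated F tests, and consecutive times with contrasts. SE values are those of the moderated fit and SD values are over 3 replicates. The main fit treats the 3 fractions of an extract as independent arrays. Where they deviate together, SE and p-values of a level are too small, and those of a loading or a comparison of fractions too large.

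Lists of genes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, where at least 5 members were measured. The 21 tests of 3 contrasts and the 56 tests of 8 consecutive contrasts were adjusted as separate families. Of 26 lists, 24 had measured members. The lists cover the clock, clock outputs, cytosolic and plastid ribosomal proteins, translation factors, light harvesting, photosystems, the Calvin cycle, chlorophyll synthesis, starch breakdown, starvation, flavonoids, nitrate and sulfate assimilation, heat, cold and wound responses, auxin and growth, the cell cycle, the proteasome, upstream open reading frames, markers of root and of stomata, and plastid and mitochondrial transcripts. Lists of seed and of vascular markers had 0 measured members. The lists, comparisons, filter and most of the alternatives were chosen before the data were examined. A further 18 families of named genes were added before any result was seen, and a list of 15 iron-deficiency genes after. Adjusted p-values of the 18 families were taken over their tests together with those of the first lists. They are therefore not from the families of 21 and 56 tests. Named genes are the 8 largest rises and 8 largest falls with the same sign in all 3 replicates (2 of each for consecutive times), the 3 list members with the smallest p and the clock genes, and the text gives a part of them.

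Whether equal replicate numbers pair the fractions of 1 extract was checked on the values: after group means were removed, all 36 pairs of fractions with the same time and number correlated above the threshold of 0.1 (median r = 0.42). Numbers therefore pair fractions within a time, and the 12 extracts were used as a block in alternatives, as fixed terms or with a consensus correlation of 0.355. Equal numbers also correlated across times, more weakly. In the same fraction at different times the median r was 0.15, with 33 of 54 pairs above 0.1. For different numbers it was -0.05, with 7 of 108 above. The numbers may thus mark series that run across the times, and the 12 extracts may not be independent. Other alternatives were no filter, a filter at 7, median centring, cyclic loess, quantile normalization, a trended robust fit, the replicate number as a block, 3 other definitions of loading, the level in 1 fraction alone, only the arrays in a contrast, 1 probe set per gene, and leaving out each array or replicate number. Added after the data were seen were averaging the fractions of an extract, leaving out the 6am or 12am arrays, and shifting arrays to equal signal of poly(A) spike-in probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

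The precision was tested on simulated data with the group structure and spread of these arrays, with independent arrays (deviations shared within an extract were not simulated). Of 67 probe sets changed by a log2 difference of 0.5, 49 were recovered for large against non-polysomal, 60 for light against dark level and 7 for light against dark loading. At a difference of 1 the numbers were 67, 67 and 52 of 67, and at 2 they were 66, 66 and 65 of 66. False calls were 3.4%, 4.0% and 4.6% of the calls. The median SE was 0.106, 0.087 and 0.212, and 0.300 for loading between consecutive times, so small changes of loading are mostly missed in this fit. Deviations shared within an extract would make the level results less reliable than simulated. For loading the main fit misses more than a paired fit: with the 12 extracts as a fixed block 4499 probe sets changed over the 4 times, against 1599.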

Results

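Aerial parts of 10-day-old Arabidopsis plants that overexpress CIRCADIAN CLOCK ASSOCIATED 1 (CCA1-ox, Columbia background) were profiled over one day. CCA1 is a MYB-type transcription factor of the morning loop of the plant circadian clock. Plants grew on agar with sucrose under 16 h of light and 8 h of dark, and were harvested at 6am, when the lights came on, at 12pm, at 6pm and at 12am. At each time RNA was separated on sucrose gradients into a non-polysomal fraction (not bound by several ribosomes), a small polysomal fraction and a large polysomal fraction, and each fraction was hybridised to its own array. The 36 arrays form 12 groups of 3 replicates, 1 group for each of the 4 times and 3 fractions. The labels do not say whether replicates came from separately grown plants, so p-values measure the spread between these samples, which may be partly technical. Wild-type plants, which the design also names, are not analysed here, so no value below separates the effect of the transgene from the daily cycle itself. The level of CCA1 is not reported, because no probe set used here carries its name alone.

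Within a group, the 3 arrays correlated with r between 0.961 and 0.996 over the probe sets kept by the filter. No 2 arrays of a group held identical values, and the number of arrays limits the precision of every difference. The first principal component carried 38.5% of the variance and followed mainly the fraction (share of its variance between fractions 0.761, between times 0.223). The second carried 29.8% and split the 2 times in the light from 12am and 6am within each fraction, while 12pm and 6pm overlapped. After the filter on low values 12635 probe sets were tested, of which 6824 name 1 gene, 263 name several and 5548 have no gene name here.

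**Figure D1:**
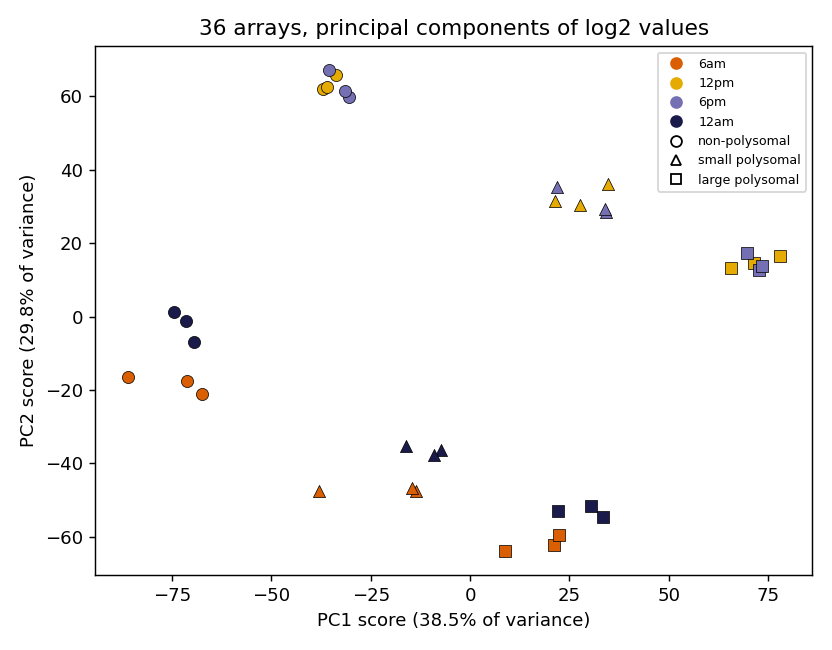
Scores of the 36 arrays on the first 2 principal components of the log2 values, 1 point per array, with colour for the time of harvest and marker shape for the fraction. The axes carry 38.5% and 29.8% of the variance, and the 3 replicates of a group lie near each other.

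The first question was which transcripts differ between the large polysomal and the non-polysomal fraction, on average over the 4 times. A lower value on large polysomes does not show that a transcript is off polysomes, because this contrast leaves out the small polysomal fraction. The lengths of coding regions were not taken into account. Transcripts of the plastid genome, which are translated on ribosomes of the plastid, gave less signal on large polysomes: 58 of 66 measured members were lower in the large polysomal than in the non-polysomal fraction and 1 was higher, with a median log2 difference of -1.50. Labelling began with oligo(dT), so plastid and mitochondrial values cover only the RNA that oligo(dT) primes. How well this stands for the whole of these transcripts was not tested, for fractions, level or loading. psaC, a photosystem I subunit, was 42.0-fold lower (log2 difference -5.39 ± 0.41, SE, n = 3 per group), petG of the cytochrome b6f complex 26.1-fold lower (-4.70 ± 0.29) and ndhG of the plastid NADH dehydrogenase-like complex 19.5-fold lower (-4.29 ± 0.37). All 5 measured mitochondrial transcripts were also lower there (median -1.92), among them nad1 (-2.68 ± 0.19), whose large polysomal means lay near the lower end of the scale. In contrast, all 5 measured nuclear genes for photosystem and chloroplast ATP synthase subunits were higher there, with PSBY at 0.89 ± 0.09 and PSBW at 0.52 ± 0.07.

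Among nuclear transcripts, all 4 measured genes of the cold response, too few for a list test, were higher on large polysomes, including the dehydrin gene COR47 (8.43-fold, log2 difference 3.08 ± 0.11), COR15B (2.47 ± 0.22), which encodes a chloroplast cryoprotective protein, and the dehydrin gene LTI30 (2.38 ± 0.26). The late embryogenesis abundant gene M17 was higher as well (3.73 ± 0.36). The largest rise was that of AT1G64370 (41.9-fold, 5.39 ± 0.15), whose non-polysomal means of 3.94 to 4.80 lay under the filter value of 5. LTI30, M17, AT2G40010 and AT5G15950 also had group means under 5, so the sizes of these differences are less certain than the others. Transcripts of cytosolic ribosomal proteins were split: 31 of 104 were higher and 58 lower on large polysomes, with a median of -0.30. The members with the smallest p were RPS25D (AT4G34555, 1.84 ± 0.08) and RPS7A (AT1G48830, 1.73 ± 0.08), which were higher, and RPP0A (AT2G40010, -3.37 ± 0.15), which was lower. Of 5 measured transcripts with conserved upstream open reading frames 4 were higher, among them the S-adenosylmethionine decarboxylase genes AT5G15950 (2.14-fold) and SAMDC (0.67 ± 0.11). Both measured clock genes were higher on large polysomes, GIGANTEA (GI) by 1.26 ± 0.12 and REVEILLE 6 (AT5G52660) by 0.64 ± 0.11. The clock output gene COR27 was lower (-1.48 ± 0.10).

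In all, 10124 of 12635 probe sets differed between the large polysomal and the non-polysomal fraction at an adjusted p under 0.05 (limma), 5342 higher and 4782 lower, and 3634 by at least 2-fold. The small polysomal fraction differed from the non-polysomal fraction at 8635 probe sets, and the large from the small polysomal fraction at 7010. By camera with a preset correlation the plastid (adjusted p = 6.8e-09), mitochondrial (0.021) and cytosolic ribosomal protein (0.019) lists lay below the other probe sets. With an estimated correlation the adjusted p was 0.50, 0.50 and 0.71, so none of these calls held. The ribosomal protein list was also not called with cyclic loess (0.057), with 1 probe set per gene (0.051) or without the 12am arrays (0.068). The nuclear photosystem list (adjusted p = 0.13), the upstream open reading frame list (0.19), the plastid ribosomal protein list (0.94, with 2 of 5 higher and 1 lower) and the auxin and growth list (0.98, with 2 of 5 higher and 1 lower) were not called. The photosystem list was called with no filter (0.018) and with quantile normalization (0.045). The other test, fry, asks whether a list changed at all, not whether it differs from the other probe sets. Its adjusted p was 3.2e-09 for the photosystem and 9e-13 for the upstream open reading frame list. With 10124 of 12635 probe sets called, these fry values do not set the 2 lists apart. All of these differences are relative to the average of each array: on arrays shifted to equal signal of poly(A) spike-in probe sets, an alternative added after the data were seen, 12424 of 12445 called probe sets were higher on large polysomes, and the medians of the plastid and mitochondrial lists became 1.12 and 0.70.

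The next question was which transcripts follow the light and dark phases. The mean of the 3 fractions stood for the level of a transcript, and the mean of 12pm and 6pm was compared with the mean of 12am and 6am. Fractions of an extract deviate together, which the main fit ignores, so the SE and p-values of levels are too small. With the 12 extracts as a random block 8094 probe sets were called for light against dark, against 9179 in the main fit. AT3G44450, which encodes BLUE-LIGHT INHIBITOR OF CRYPTOCHROMES 2, was higher in the light (log2 difference 5.03 ± 0.14, n = 3 per group, higher in all 3 replicates). The pectin lyase-like genes AT1G60590 (4.98 ± 0.08) and AT1G10640 (4.61 ± 0.12) followed. Genes of the iron-deficiency response were also among the largest rises, with AT1G47400, which encodes the peptide IRON MAN 1, at 4.45 ± 0.20 and the transcription factor gene BHLH101 at 3.94 ± 0.14. In the dark, the clock- and cold-regulated genes COR27 (-4.65 ± 0.08, 25.2-fold) and COR28 (AT4G33980, -3.58 ± 0.12) were higher than in the light, as was XTH33, which encodes a cell wall xyloglucan endotransglucosylase (-4.21 ± 0.16). Of the genes named in this paragraph only COR27 stayed above 5 in every group. The others fell to means between 2.37 and 3.97, near the lower end of the scale, so their direction is clear but the size of the difference is not.

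Of 21 listed clock genes 2 were measured, and they changed less than the genes above, which were picked for their large changes. GI was 2.00-fold higher in the light (1.00 ± 0.10) and AT5G52660 1.62-fold higher (0.69 ± 0.09). GI rose from 6.17 at 6am to 7.29 at 12pm in the non-polysomal fraction and from 6.68 to 8.47 in the large polysomal fraction.

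Genes for photosynthesis rose in the light with small changes. All 5 measured photosystem and ATP synthase genes rose (median 0.56, ATPC1 at 0.98 ± 0.08, PSAN at 0.62 ± 0.05), as did all 3 Calvin cycle genes, SBPASE (0.63 ± 0.07), PRK (0.58 ± 0.09) and RCA (0.36 ± 0.10), and all 3 light-harvesting genes, with LHCB4.2 at 0.50 ± 0.07. Of the plastid transcripts 36 of 66 fell in the light and 0 rose (median -0.36), psbB by -1.10 ± 0.15. From the large polysomal fraction alone psbB was at -0.61 and not called (limma, adjusted p = 0.051). All 4 measured genes of DNA replication and mitosis rose, among them PROLIFERA (PRL), a subunit of the replicative helicase, at 1.18 ± 0.10. Both flavonol glycosyltransferase genes, UGT78D1 (1.22 ± 0.13) and UGT78D2 (0.69 ± 0.09), rose. Of 5 genes of auxin response and cell expansion 4 fell, with IAA29 at -3.41 ± 0.09 and GH3.3 at -1.99 ± 0.18, while the expansin gene EXPA8 rose by 2.34 ± 0.09. The 1 measured starvation gene, MCCA of leucine breakdown, fell by 2.64 ± 0.08. Of 5 transcripts with conserved upstream open reading frames 3 rose, AT5G15950 by 2.42 ± 0.10, and 1 fell. Of the cold genes COR15A (2.28 ± 0.21) and COR15B (2.26 ± 0.18) rose and COR47 fell (-0.79 ± 0.09).

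The remaining groups changed less or in both directions. Of 104 cytosolic ribosomal protein genes 31 rose and 21 fell (median 0.05). Of 5 plastid ribosomal protein genes 3 rose, of 4 chlorophyll synthesis genes 1 rose, of 4 proteasome genes 2 fell, of 3 translation factor genes 1 rose and 1 fell, of 3 heat-response genes 1 rose and 1 fell, and of 5 mitochondrial transcripts 1 rose and 1 fell. Neither of 2 starch breakdown genes, nor SIR (-0.32 ± 0.16) of sulfate assimilation, nor STZ (0.24 ± 0.43) of the wound response was called. SIR was close to the threshold: it was called with replicate numbers as a block (adjusted p = 0.023), without the 6am arrays (-0.41), without replicate 3 (-0.56) and without any 1 of 8 single arrays. The root marker PYK10 rose by 0.43 ± 0.09 and the stomatal marker FMA fell (-0.49 ± 0.09), but neither was called without the 6am arrays (0.01 and -0.15). PYK10 was also not called from the large polysomal fraction alone (0.21).

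Between light and dark 9179 of 12635 probe sets differed (limma, adjusted p under 0.05), 4564 higher and 4615 lower in the light, 1782 by at least 2-fold. This even split is relative to the array average: on arrays shifted to equal spike-in signal 5251 were higher and 866 lower, around a median of all probe sets of 0.41. When the 3 fractions of an extract were averaged first, 7838 probe sets differed between light and dark. By camera the photosystem (adjusted p = 0.018), upstream open reading frame (0.036) and plastid transcript (0.018) lists were called. With an estimated correlation the adjusted p was 0.46, 0.44 and 0.71. With the 12 extracts as a random block the plastid list was not called (adjusted p = 0.066), while the other 2 were. The auxin and growth list was not called in the main fit but was in 6 of 30 alternatives. Among these were the random block (median -1.07, adjusted p = 0.029), no filter (0.031) and the fit without the 12am arrays (-1.95, adjusted p = 0.043). The median level of this list was 8.84 at 6am but 7.38 at 12am, against 7.12 at 12pm and 7.25 at 6pm. Much of its fall in the light therefore rests on the 6am level. The upstream open reading frame list was not called with cyclic loess (0.052), from the large polysomal fraction alone (0.067), without replicate 3 (0.066) or without the 12am arrays (0.094), where AT5G15950 was at 0.98, against 3.86 without the 6am arrays. The photosystem list was not called from the large polysomal fraction alone (0.13), and the plastid list neither from that fraction (-0.22, adjusted p = 0.21) nor from the small polysomal fraction (-0.33, adjusted p = 0.050). Without the 6am arrays, an alternative added after the data were seen, the median of the plastid transcripts was -0.07 and that of the photosystem genes 0.35, and neither list was called. The light rise of carbon fixation and light-harvesting genes also rested on the 6am level: without those arrays SBPASE was at 0.00, RCA at -0.14, PRK at 0.05 and LHCB4.2 at 0.07, and none of the 4 was called. RCA was also not called without replicate 2 (adjusted p = 0.051) or 3 (0.15, adjusted p = 0.19), or from the non-polysomal or small polysomal fraction alone (0.097 and 0.085).

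**Figure D2:**
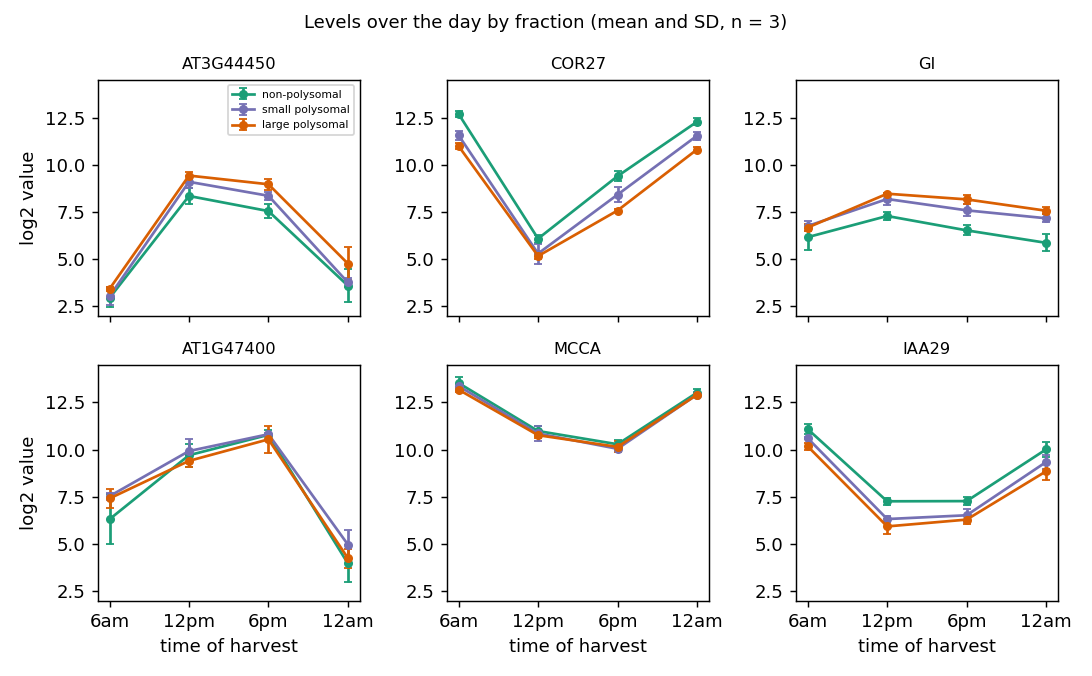
Mean log2 value of 6 genes at the 4 times of harvest in the non-polysomal, small polysomal and large polysomal fraction, with bars of 1 SD over 3 replicates. COR27 falls from 12.69 at 6am to 6.09 at 12pm in the non-polysomal fraction and AT3G44450 rises from 2.95 to 8.35.

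Step by step through the day, more probe sets changed from 6am to 12pm, when the lights went on, than in any other step. On arrays shifted to equal spike-in signal this did not hold, with 3497 called from 6am to 12pm and 5195 from 6pm to 12am. From 6am to 12pm AT3G44450 (5.82 ± 0.20) and AT1G13650 (5.55 ± 0.12) rose, while COR27 (-6.23 ± 0.12) and AT5G02580 (-4.66 ± 0.25) fell. Over the same step 54 of 66 plastid transcripts fell (median -0.83), all 5 photosystem genes rose (median 0.89) and 4 of 5 auxin and growth genes fell (median -2.01). From 12pm to 6pm COR27 began to return (2.94 ± 0.12), the zinc finger gene STZ rose (2.86 ± 0.60, but adjusted p = 0.074 with averaged extracts), and AT1G13650 (-2.00 ± 0.12) and AT3G46370 (-1.72 ± 0.12) fell. STZ was also not called without replicate 2 (2.35), or from the non-polysomal, small or large polysomal fraction alone (limma, adjusted p = 0.052, 0.16 and 0.14). Of the cytosolic ribosomal protein genes 36 of 104 rose in this step, and the median change of all 104 was 0.15. From 6pm to 12am XTH33 (4.24 ± 0.23) and AT4G33980 (4.19 ± 0.17) rose, and AT1G47400 (-6.31 ± 0.29) and AT1G60590 (-5.14 ± 0.12) fell. From 12am to 6am the bZIP gene HYH, a relative of the light-signalling gene HY5, (3.22 ± 0.19, 9.32-fold) and AT4G15430 (3.19 ± 0.16) rose, AT2G47880 (-2.83 ± 0.22) and the elongation factor gene AT5G12110 (-2.81 ± 0.25) fell, 40 of 66 plastid transcripts rose (median 0.67) and all 5 auxin and growth genes rose (median 1.23). Of the single genes named for these steps only COR27 and HYH stayed above 5 in every group, so for the others the size of a change is less certain than its direction.

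Across the 4 times, the mean level of 10940 of 12635 probe sets changed (moderated F test of limma, adjusted p under 0.05). This became 8912 when the 3 fractions of an extract were averaged first. Taken alone, the non-polysomal fraction changed at 8669 probe sets, the small polysomal fraction at 7740 and the large polysomal fraction at 7467. Without replicate 2 of every group these became 5360, 4575 and 4510. The steps changed 8429 (6am to 12pm), 3865 (12pm to 6pm), 7446 (6pm to 12am) and 6135 (12am to 6am) probe sets. The afternoon step was the least stable of these counts: it was 1625 with the 12 extracts as a random block, 729 when the 3 fractions of an extract were averaged first, and 829 without replicate 2. The step from 12am to 6am came to 3898 with averaged extracts and 3708 without replicate 2. With averaged extracts the steps to 12pm and to 12am came to 6909 and 5651. By camera the plastid list was called for 6am to 12pm (adjusted p = 3e-05) and 12am to 6am (5.5e-06), the photosystem list for 6am to 12pm (0.0074, but 0.082 in the large polysomal fraction alone), the auxin and growth list for both (0.045 and 0.0011, the former 0.067 with replicate numbers as a block) and the cytosolic ribosomal protein list for the afternoon step (1.6e-05). The cytosolic ribosomal protein list was also called from 6pm to 12am (median -0.18) and 12am to 6am (0.13). So was the photosystem list from 12am to 6am (-0.54). The upstream open reading frame list was called from 6pm to 12am (-0.9). The plastid (0.2) and plastid ribosomal protein (0.29) lists were called from 12pm to 6pm. From the non-polysomal fraction alone the ribosomal protein list (12am to 6am) was at -0.12 and the plastid list (12pm to 6pm) at -0.23, neither called. With an estimated correlation the adjusted p of these calls lay between 0.22 and 0.86.

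The last question was whether ribosome loading, the log2 large polysomal minus the log2 non-polysomal value of a transcript, changed over the day. Loading at 6am, the end of the night, stood apart from the other 3 times. Transcripts of cytosolic ribosomal proteins had a median loading of 0.10 ± 0.25 (SD, n = 3) at 6am against -0.39 ± 0.11 at 12pm, -0.39 ± 0.11 at 6pm and -0.43 ± 0.20 at 12am. From 12am to 6am the loading of 31 of 104 rose and of 0 fell (median change 0.52), and from 6am to 12pm that of 22 fell and of 0 rose (median change -0.48). The 5 photosystem genes had a median loading of 0.81 ± 0.07 at 6am and of 0.07 ± 0.09 at 12pm, and 3 of them fell over that step (median change -0.72).

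**Figure D3:**
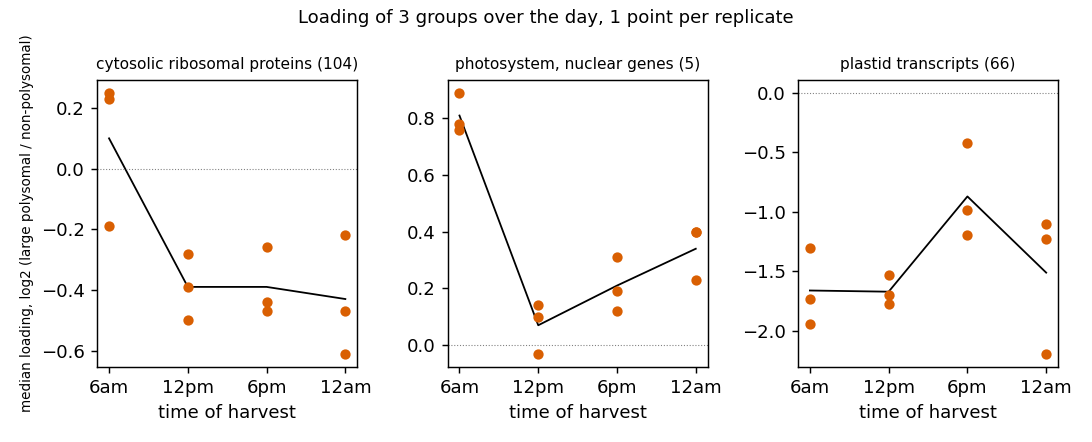
Median loading (log2 large polysomal minus log2 non-polysomal) of 104 cytosolic ribosomal protein genes, 5 photosystem genes and 66 plastid transcripts at the 4 times of harvest, 1 point per replicate and a line through the mean of 3 replicates. For the ribosomal protein genes the mean is 0.10 at 6am and between -0.43 and -0.39 at the other times, and 1 of the 3 replicates at 6am lies at -0.19.

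In the light against the dark, single genes changed loading in both directions. Of those measured above the filter value in every group, AT5G57370 rose in loading (2.63-fold, SE of the log2 difference 0.16, n = 3 per group) and AT2G14900 (-1.39 ± 0.21) fell. AT5G57370 was not called with the small in place of the large polysomal fraction (0.65), nor AT2G14900 without the 6am arrays (-0.78), replicate 2 (-1.33) or replicate 3 (-1.17). AT5G28630 (-2.52 ± 0.25) and the expansin gene EXPA16 (-2.15 ± 0.27) fell in loading. In both cases it was the large polysomal level that differed, with EXPA16 at 7.42 at 6am and 3.57 at 12pm, while the non-polysomal means of both genes lay under 5 throughout. With the small in place of the large polysomal fraction neither was called (-0.98 and -0.43), and EXPA16 was not called without the 6am arrays (-0.98). The largest rise, that of AT1G23650 (3.11 ± 0.37), followed its non-polysomal level (6.84 at 6am, 2.68 at 12pm), because its large polysomal means of 2.18 to 2.36 lay at the lower end of the scale at all times. At 12am the small heat shock protein gene AT1G53540 reached 7.27 in the large polysomal fraction, against 2.79 at 6pm and 2.51 at 6am, and its loading rose from 6pm to 12am (3.63 ± 0.61) and fell from 12am to 6am (-3.67 ± 0.61). Because the values at 6pm and 6am lie near the lower end of the scale, the size of these changes is uncertain. The first of these calls was lost without any 1 of the replicate numbers (4.08, 3.39 and 3.43 without 1, 2 and 3), with only the arrays in the contrast, and with loading from the linear sum (2.99) or the small polysomal fraction (1.62). The second was lost without replicate 2 (-3.21) and with the small polysomal fraction (-1.30). GI (0.31 ± 0.25) and AT5G52660 (0.36 ± 0.22) were not called, but GI was without the 12am arrays (0.91, adjusted p = 0.044), and AT5G52660 was without replicate 1 (0.76, adjusted p = 0.023).

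Loading changed over the 4 times at 1599 of 12635 probe sets (moderated F test of limma, adjusted p under 0.05), and between light and dark at 691, 262 higher and 429 lower in the light. With cyclic loess the latter split was 347 higher and 331 lower, and with median centring 327 and 348. By steps, 861 changed from 6am to 12pm (301 higher, 560 lower), 0 from 12pm to 6pm, 7 from 6pm to 12am and 1074 from 12am to 6am (656 higher, 418 lower). With cyclic loess the split was 370 and 386 for the step from 6am to 12pm and 479 and 496 for that from 12am to 6am. For the afternoon step 1452 probe sets had an unadjusted p under 0.05. Fractions of 1 extract deviate together, and with the 12 extracts as a fixed block the counts were 4499 for the 4 times, 2060 for light against dark, and 2484, 512, 174 and 2822 for the steps. They also depended on which arrays were used: without the 6am arrays 80 probe sets changed over time and 64 between light and dark, and without replicate 2 of every group 25 and 17, without replicate 3 234 and 26, and without replicate 1 2165 and 1551. Leaving out 1 array gave 418 to 1452 for the step from 6am to 12pm and 440 to 1814 for that from 12am to 6am.

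By camera the ribosomal protein list was called for both steps around 6am (adjusted p = 5.4e-15 from 12am, 8.9e-14 to 12pm) and for light against dark (2.6e-06, median -0.21, with 9 of 104 lower in the light), and the photosystem list likewise (0.021, 0.0064 and 0.019, with a light against dark median of -0.46). With an estimated correlation the adjusted p was 0.37 for the steps, and 0.50 and 0.46 for light against dark. By fry, which tests the direction of a list alone, the adjusted p for the ribosomal protein list was 0.0029, 0.0052 and 0.053. With cyclic loess the ribosomal protein medians were smaller, at 0.24 and -0.18 for the steps and -0.11 for light against dark, and still called at the preset correlation. Without the 6am arrays the light against dark median was 0.05 for the ribosomal protein list and -0.20 for the photosystem list. With cyclic loess the photosystem list was not called for light against dark (0.15) or for either step, with medians of -0.25, -0.26 (to 12pm) and 0.10 (to 6am), and without the 6am arrays it was not called for light against dark (0.48). The step from 12am to 6am was also not called for this list with quantile normalization (0.083) or under the 3 other definitions of loading (0.06 to 0.38). The plastid transcripts showed a higher median loading at 6pm than at 12pm (0.85, adjusted p = 3.9e-12) and a lower one at 12am than at 6pm (-0.55, 1.7e-08), and in the light than in the dark a higher one (0.26, 0.003), but 0 of 66 members passed the test for a single probe set and the adjusted p was 0.43, 0.63 and 0.71 with an estimated correlation and 0.11, 0.27 and 0.41 by fry.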

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

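The tests of single 6am extracts, of the spike-in probe sets and of cyclic loess on the ribosomal protein list, the contrast of 6am with the other times and the fits without the 6am arrays were chosen after the result was seen.

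What stood out here is that the difference between large polysomal and non-polysomal RNA depended on the time of day. The difference was tested directly and called at 1599 probe sets over the 4 times, 691 for light against dark, 861 from 6am to 12pm, 7 from 6pm to 12am and 1074 from 12am to 6am. In lists, the median loading of the photosystem genes changed by -0.46 in the light, by -0.72 from 6am to 12pm and by 0.47 from 12am to 6am, and that of the cytosolic ribosomal protein genes by -0.48 and 0.52 over the last 2 steps. None of these list calls held with an estimated correlation (adjusted p = 0.46 for light against dark and 0.37 for the steps), and with cyclic loess the medians were -0.25, -0.26 and 0.10 for the photosystem genes and -0.18 and 0.24 for the ribosomal protein genes. The probe sets of poly(A) spike-ins, which no comparison used, also differed between fractions, with a mean difference of -2.62 between large polysomal and non-polysomal arrays.

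Loading at 6am differed from the mean of the other times at 2266 of 12635 probe sets, 1343 higher and 923 lower. Less clean separation of the fractions at 6am could shrink all loadings alike, and the slope of the 6am loading on the others was 0.83. After dividing each time by its slope 3834 probe sets were called, against 3267 in the same fit without the division. An equal shrinkage is therefore not the whole cause. Carry-over between fractions need not act as 1 slope on the log2 scale, so poor separation is not excluded. Cyclic loess gave 2206 (1073 higher, 1133 lower), which argues against the normalization as the whole cause, and leaving out 1 of the 6 arrays gave 1355 to 2969, although without replicate 2 of every group 80 were called and without replicate 3 596. Signs of quality also differed at 6am: the 3 non-polysomal arrays had the lowest r (0.961 to 0.966) and the largest median SD (0.316) of the 12 groups, and large minus non-polysomal was -3.39 (SD 1.72) for 25S rRNA (-1.04 to -1.33 at the other times), -5.11 for 5S rRNA (-1.86 to -4.01) and -0.87 for hybridization controls (-0.47 to -0.62). A change in translation at the end of the night may underlie the pattern, but a difference in the handling or RNA composition of the 6am fractions could too, and with 1 harvest time each the design does not separate them.

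Cytosolic ribosomal protein mRNAs had a loading 0.48 higher at 6am than at the other times (median of 104), a list call that does not hold with an estimated correlation (adjusted p = 0.20). Of 10000 random lists of matched signal, with medians from 0.03 to 0.47 around 0.24, none was as high (percentile 100, only descriptive because members vary together), so about 0.24 of the rise is shared with equally bright probe sets. Cyclic loess, which removes trends with signal, left a median of 0.20, so much of the rise depends on the normalization. The lowest median without 1 of the 3 extracts was 0.40, so no 1 extract accounts for the rise. After the division by slopes the median was 0.48. With a median loading of 0.10 at 6am that division could change little, so it does not decide on poor separation. The normalization therefore stays open as a source of much of the rise, as do the separation of the fractions and the handling of the 6am harvest. Greater ribosome loading before dawn was not separated from them.

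The spike-in probe sets were lower on the large polysomal array in 12 of 12 extracts (-2.62, SD 0.49). Overall array brightness would move the hybridization controls, added after labelling, by the same amount, but these differed by -0.63, which leaves -1.99 (SD 0.58, range -2.69 to -0.76). If spike-ins were added in equal amounts, which the labels do not state, more mRNA may have been labelled from the large polysomal fraction, and all log2 differences between fractions would be relative to that. No biological explanation was tested. On a spike-in scale 2 probe sets rather than 2266 were called for 6am against the other times, because the shift raised the median SE from 0.24 to 0.66, while the ribosomal protein median was 0.70 (SE 0.65) instead of 0.48 (SE 0.20).

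Other splits of the samples, 100 drawn including the real one, gave fewer calls than the real one. For the fractions and the level this argues against chance. The real count and the highest of the others were: large against non-polysomal 10124 and 7564, small against non-polysomal 8635 and 6738, large against small polysomal 7010 and 5359, time on the level 10940 and 7759, light against dark level 9179 and 6706, time in the non-polysomal 8669 and 3255, small 7740 and 2289 and large polysomal fraction 7467 and 2459. For loading they were 1599 and 229 over time and 691 and 9 for light against dark, but these do not decide. Mixing the times puts real changes of level into the spread, which by itself lowers the loading counts of the other splits. In each case 1 split, the real one, gave as many. For consecutive times there are 10 splits of 6 extracts, too few for a share under 0.05. Their real and highest other counts were, for the level, 8429 and 1151, 3865 and 1159, 7446 and 26, and 6135 and 1980, and for loading 861 and 0, 0 and 1, 7 and 0, and 1074 and 0.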

How the results depend on the processing

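The averaged extracts, the fits without the 6am or 12am arrays and the spike-in shift were chosen after the result was seen. Of 969 recomputed counts 845 stayed within 1.5 times the value reported. Of 1044 recomputed list results 928, and of 4047 recomputed values of named genes (spike-in shift not included) 4002, kept the side of the threshold. They also kept direction wherever a value was called. A change of sign between values that were not called counted as kept, as for the level of STZ in the light (-0.2 to 0.69). Most alternatives for counts and genes leave out 1 array. Unless a reason is given, the cause was not tested. With a filter at 7, which removes low signal, 1581 probe sets were called for time on loading, against 1599.

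With 1 probe set per gene fewer probe sets are tested (6804), and the counts, in the order fractions, times, light against dark, single fractions and steps, were 5460, 4652, 3812, 5853, 4927, 4547, 4008, 3904, 4516, 1859, 3940 and 3191, and for loading 907, 390, 495, 4 (6pm to 12am) and 614. The spike-in shift gave 12382 for large against small polysomal, 6387 for time and 6117 for light against dark, 2719, 1322 and 2351 in the fractions, 3497, 716 and 910 for the steps to 12pm, 6pm and 6am, and for loading 1 over time, 4 for light against dark and 0 for the steps to 12pm, 12am and 6am. Under it medians turned to 2.32 (ribosomal proteins), 1.12 (plastid) and 0.70 (mitochondria) for large against non-polysomal and 0.07 for plastid transcripts in the light. Without the 6am arrays the ribosomal protein loading median for light against dark turned to 0.05, and SBPASE (0.00) and RCA (-0.14) lost their rise.

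The level steps to 6pm, 12am and 6am depended on the fraction used: 1478 and 4466 (first 2 steps) from the non-polysomal, 599, 4302 and 2884 from the small and 184, 4826 and 2669 from the large polysomal fraction. The step to 6pm was 1625 with the 12 extracts as a random replicate block and 729 with averaged extracts, which gave 3898 for the step to 6am.

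For loading (time, light against dark, steps to 12pm, 6pm, 12am and 6am) the block of 12 extracts gave 4499, 2060, 2484, 512, 174 and 2822 when fixed and 4385, 2010, 2455, 477, 157 and 2806 when random, and the replicate block of 3 numbers 2635, 1116, 1464, 70, 35 and 1638. A loading from the mean of both polysomal fractions gave 953, 365, 450 and 520 (time, light against dark, steps to 12pm and 6am), from their linear sum 485, 149, 177, 2 (to 12am) and 246, and from the small polysomal fraction 22, 10, 10, 0 (to 12am) and 16. With only the arrays of a contrast, which are fewer, the steps gave 70, 1, 4 and 212. No filter gave 36 and 59 for the steps to 6pm and 12am, and a filter at 7 gave 0 for the latter. Without the 6am arrays 80 and 64 were called over time and for light against dark, and without the 12am arrays 1948 for the latter.

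Leaving out a replicate number leaves 2 per group. The ranges over single numbers and arrays were 5360 to 8788 (non-polysomal), 4575 to 7916 (small) and 4510 to 7669 (large polysomal) for time in the fractions, 829 to 4081 and 3708 to 6195 for the level steps to 6pm and 6am, and for loading 25 to 2211 (time), 17 to 1551 (light against dark), 20 to 1618 and 9 to 1814 (steps to 12pm and 6am), 0 to 10 (to 6pm) and 2 to 13 (to 12am). Without replicate 2 the counts were lowest for each of these but the loading step to 6pm. Single arrays moved loading counts by over 1.5 times: light against dark 454 without 6pm large polysomal replicate 3. The step to 12pm was 1452 and 527 without 6am non-polysomal replicates 1 and 3, 428 and 460 without 12pm non-polysomal replicates 2 and 3, 418 without 6am and 466 without 12pm large polysomal replicates 1 and 3. The step to 6am was 1814 and 523 without 6am non-polysomal replicates 1 and 3, 440 without 12am non-polysomal replicate 1, 632 and 609 without 6am large polysomal replicates 1 and 2, and 577 and 653 without 12am large polysomal replicates 2 and 3.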

Other observations

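The iron-deficiency list and its test were chosen after the result was seen, and the families named here were added before any result.

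Some further values concern groups that the report gives in part or not at all. The 6 measured LSM genes, whose proteins bind RNA in mRNA decay and splicing, had a median loading of 0.05 ± 0.05 (SD, n = 3) at 6am against -0.84 at 12pm, -0.94 at 6pm and -0.87 at 12am, and 3 of 6 rose from 12am to 6am (adjusted p = 0.004 by camera, 0.79 with an estimated correlation). The 6 RALFL genes, which encode small signalling peptides, stood at 0.18 at 6am and between -0.91 and -0.76 at the other times (adjusted p = 0.018 from 12am to 6am, 0.80 with an estimated correlation). From the small polysomal fraction neither family was called for that step (LSM 0.19, adjusted p = 0.071, RALFL 0.39, adjusted p = 0.052), and RALFL was also not called with cyclic loess (0.68, adjusted p = 0.050), without replicate 1 (0.059) or without 6am non-polysomal replicate 3 (0.073). The median loading of the 3 measured heat-response genes was 2.09 ± 0.40 at 12pm, 2.94 ± 0.47 at 12am, 0.07 ± 0.44 at 6am and 0.43 ± 0.24 at 6pm. These genes are too few for a list test, their median level of 4.39 to 5.41 lies around the filter value of 5, and AT5G37670 did not differ between the fractions over the 4 times at adjusted p under 0.05 (0.05 ± 0.12). Of 10 ESCRT genes of vesicle sorting 8 were higher on large polysomes and 1 lower (median 1.09, adjusted p = 0.06). This list was called with the 12 extracts as a fixed (0.048) or random block (0.044), with no filter (0.0069), with only the arrays of the contrast (0.045), with 1 probe set per gene (0.045) and without the 12am arrays (0.043), but not with an estimated correlation (0.69). Of 13 expansin and XTH genes of the cell wall 10 fell and 3 rose in the light (median -1.29, adjusted p = 0.69 with an estimated correlation), with EXLA1 at -3.43 ± 0.13 and XTH32 at 3.26 ± 0.09.

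AT1G47400 and BHLH101, both of the iron-deficiency response, were among the largest rises in the light, so a shared light rise of that response was a candidate explanation. Of 15 genes listed 4 were measured, and of the 2 others 1 was higher in the light: PYE rose by 1.82 ± 0.09 (3.53-fold), while AT1G18910 fell by 0.23 ± 0.07. AT1G18910 stayed close to the filter value of 5 at all times (5.49 at 6am, 4.97 at 6pm), so it carries little weight. A rise of every measured member was not seen, and a shared rise of part or all of the response stays possible. AT1G47400 went from 7.09 at 6am to 10.71 at 6pm and 4.40 at 12am, and BHLH101 from 4.52 to 8.82 and 3.68.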
